A study of Mus musculus with 2 samples.

How the data were processed

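Total RNA from 2 pools of 100 CMP was sequenced, RNA over 200 nucleotides being kept and 2 sets of spike-ins added, per the labels. The replicate numbers come from the labels, which name both libraries as biological replicates with separate biosamples and the same donor identifier. The authors aligned reads to the transcriptome of mouse build mm10 with GENCODE release M4 and deposited a gene table and a transcript table per library. The deposited expected counts are estimates per gene or transcript in which reads shared between genes are divided, in the column layout of RSEM, and the aligner, the quantifier and their versions are not given in the sources used here. The deposited TPM values are transcripts per 1000000 over all table entries, tRNA and spike-in entries included. The deposited FPKM values, which divide counts by transcript length and library depth, were a constant multiple of TPM within a library and were not used here. The deposited percent values give the share of its gene's TPM that each transcript takes. Lengths and effective lengths in the deposited tables are in bases.

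Gene identifiers were matched without version to GENCODE M21 on the same build (GRCm38), which gave symbols, biotypes and coordinates for 42462 of 43346 mouse genes. The 26248 tRNA entries, 96 spike-ins and 1 phiX entry were kept apart from the genes. Depth was 28916263 expected counts in replicate 1 and 26426710 in replicate 2, and 0 counts allow up to 0.104 and 0.114 counts per 1000000 (3 counts of the total). Nuclear protein-coding genes held 43.9% and 45.3% of the counts. Genes were called detected at a TPM of 1 or more. Log ratios within a library used TPM plus a pseudocount of 1, and values are given as mean and SD over both libraries.

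The 32 gene lists (CMP gate genes, lineage depletion, stem and progenitor, mature blood cell, stroma and other tissue markers, transcription factors, receptors, cell cycle, chromatin, stress, metabolism, Hox, apoptosis, non-coding RNA, sex-linked, ribosomal protein, respiratory chain, mitochondrial and histone genes), the 32 gene pairs, the tests and the rule for naming genes were fixed before the data were examined. Genes named are the 20 nuclear protein-coding genes with the highest mean TPM, the 4 highest members of each list with up to 4 members below 1 TPM in both libraries, all pairs, all gate and sex-linked genes, the 10 genes with the largest log2 ratio in each direction between the libraries among those with 50 or more counts in a library, and fixed genes for transcript shares. For shorter text, some of the 4 highest members of a list are left out, and some genes and results under the rule are not reported here. Genes outside this rule are said to be chosen after their values were seen.

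List medians were placed among the medians of 10000 random lists of protein-coding genes of the same size. Pairs were tested with limma's moderated test of the mean log2 ratio against 0, two-sided, with a variance trend estimated from 5000 random pairs of detected protein-coding genes and Benjamini-Hochberg adjustment over the 32 pairs. Genes were compared between the libraries by a two-sided exact binomial test on rounded expected counts scaled by TMM in edgeR, for genes with 10 or more counts in a library, with Benjamini-Hochberg adjustment at 0.05, spike-ins and genes annotated as ribosomal RNA being left out. Gm42418, whose annotation is long non-coding RNA, stayed among the genes tested. The dispersion was estimated in edgeR with an intercept alone. Leading transcripts were compared by Fisher's exact test in genes with 2 or more transcripts and 50 or more counts in each library. Lower bounds for folds against 0 counts use 3 counts per library. The comparison of list shifts with lists matched on level, and the counts of list members under each scaling, were chosen after the values were seen.

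The tests were checked on simulated data. For the binomial and Fisher tests the simulated counts held counting noise alone, so those rates do not carry over to the wider spread of these libraries. For the pair test the simulated values held the median spread by level of genes detected in both libraries, with normal noise. Pairs with a gene near 0 counts were not simulated, so the pair test's rates do not carry over to such pairs. The binomial test recovered 62% of 50 genes changed 1.5-fold, 86% at 2-fold and 100% at 4-fold, and called 9 of 13130 unchanged genes. Fisher's test recovered 68% of shifts of 10 percentage points and 98% of 20, and the pair test 79% of log2 ratios of 1 and 100% of 2, with 7 of 100 unchanged pairs called. Alternatives tried were other TPM thresholds, posterior mean values, TPM rescaled over nuclear protein-coding genes, a pseudocount of 0.1, DESeq2 size factors, total-count scaling, no count minimum, the edgeR exact test at the common dispersion, values without length correction, a fit without variance trend, other count minimums, protein-coding transcripts alone and leaving out each library. Sequences were searched with BLAST 2.17.0. A near-identical stretch was an alignment of 100 or more bases at 97% identity or more with another gene's transcript. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. No comparison between groups was made, because the series holds 1 group.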

Results

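Total RNA was sequenced from mouse common myeloid progenitors (CMP), bone marrow cells from which granulocytes, monocytes, red cells and megakaryocytes arise. Each of the 2 libraries was made from a pool of 100 primary cells of male C57BL/6J adults aged 5 to 6 weeks, and RNA longer than 200 nucleotides was kept. Both libraries belong to 1 group, so the series holds no contrast between conditions, and the labels state no question beyond the RNA content of these cells. The comparisons made here set genes against each other within CMP and set the 2 libraries against each other. The deposited gene tables held 28916263 expected counts for replicate 1 and 26426710 for replicate 2. A gene with 0 counts was thereby limited to 0.104 CPM (counts per 1000000) in replicate 1 and 0.114 in replicate 2, the level of 3 counts. These floors cover counting error only, because reads without molecular identifiers are not independent molecules. The labels give both libraries the same donor identifier, so every test describes the spread between these 2 libraries.

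Of the 6 genes used to sort CMP, 3 were detected at 1 TPM (transcripts per 1000000) or more in both libraries, at a list median of 4.25 ± 3.80 TPM. Kit, the stem cell factor receptor (chromosome 5, 75574916 to 75656722, GRCm38), reached 95.5 ± 3.67 TPM (SD, n = 2), and Cd34, a sialomucin of progenitors (chromosome 1, 194938819 to 194961279), reached 65.0 ± 13.5 TPM. Fcgr2b (chromosome 1, 170958617 to 170976547) and Fcgr3 (chromosome 1, 171051174 to 171064935), which encode the Fc receptors read at a low level in this gate, stood at 6.04 ± 5.03 and 2.46 ± 2.57 TPM. Ly6a, which encodes the stem cell antigen Sca-1 (chromosome 15, 74994877 to 74998031), and Il7r, the interleukin 7 receptor of lymphoid progenitors (chromosome 15, 9505788 to 9530176), had 0 counts in both libraries. Of the 10 genes behind the usual lineage depletion, 3 were detected at 1 TPM or more in both libraries. These were Ptprc, the common leukocyte antigen, at 51.9 ± 0.856 TPM, Ly6c2 at 22.2 ± 9.96 TPM and Itgam at 2.08 ± 1.26 TPM, and the list median was 0.0625 ± 0.0177 TPM. Cd3e, Cd4 and Cd8a stayed below 1 TPM in both libraries, and Cd5 had 145 counts in replicate 1 and 0 in replicate 2. Of the 8 sex-linked genes 4 were detected in both libraries (median 4.89 ± 0.845 TPM), all of them Y-linked, with Eif2s3y at 55.4 ± 13.2 TPM, Uty at 18.1 ± 3.32, Kdm5d at 12.7 ± 5.76 and Ddx3y at 12.6 ± 2.30, while Xist, Zfy1, Zfy2 and Usp9y had 0 counts.

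Programmes of both myeloid and erythroid-megakaryocyte progenitors were read in the same pools. All 16 genes of the erythroid-megakaryocyte progenitor list were detected in both libraries, with a median of 54.7 ± 3.50 TPM. Car1, a carbonic anhydrase of early erythroid cells, reached 1136 ± 70.3 TPM, Car2 404.5 ± 71.8, the LIM-domain factor Lmo2 218.4 ± 27.9 and Nfe2, a regulator of platelet formation, 126.2 ± 33.2. Of the 18 granulocyte-monocyte progenitor genes 15 were detected in both, with a list median of 15.2 ± 1.496 TPM. Mpo, the myeloperoxidase of primary granules (chromosome 11, 87793581 to 87804413), stood at 386.0 ± 0.141 TPM, and the granule protease genes Prtn3 and Ctsg at 71.3 ± 48.3 and 57.2 ± 10.9 TPM. Nkg7 stood at 66.1 ± 11.96 TPM, and Cebpe and Fcnb, which mark later granulocyte steps, stayed below 1 TPM in both libraries. The medians of both lists exceeded at least 99.67% of 10000 random lists of protein-coding genes of the same size in each library. Against random lists of detected genes alone, the erythroid-megakaryocyte list stayed at percentile 100 in each library and the granulocyte-monocyte list stood at 84.97 and 71.86. With 2 libraries no exact test across replicates was possible, the smallest sign-flip p being 0.5, so list percentiles are descriptions of these libraries.

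Genes of the list that joins stem cells and multipotent progenitors were partly present, which does not tell these cell types apart. Of the 16 stem cell and multipotent progenitor genes 10 were detected in both libraries, at a median of 3.66 ± 0.2015 TPM, among them the homeobox gene Meis1 at 50.04 ± 7.04, Cd48 at 30.6 ± 4.17 and Mllt3 at 15.1 ± 2.503 TPM. Procr, which marks long-term stem cells, had 0 counts in both libraries, and Hoxb5 stayed below 1 TPM in both. Of the 21 Hoxa and Hoxb genes 4 were detected in both libraries, namely Hoxa7 at 9.71 ± 3.32 TPM, Hoxa9 at 7.77 ± 6.17, Hoxa6 at 2.44 ± 0.134 and Hoxb4 at 2.22 ± 1.46. The median of that list was 0.0150 ± 0.0212 TPM. All 18 Hoxc and Hoxd genes had 0 counts in both libraries.

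Genes of maturing red cells and megakaryocytes stood below the erythroid-megakaryocyte and granulocyte-monocyte progenitor lists by median in both libraries. In the erythroid list 9 of 12 matched genes were detected in both libraries, with a median of 5.68 ± 1.17 TPM, among them the blood group gene Ermap at 87.4 ± 36.2, the globin gene Hba-a2 at 29.3 ± 36.7 and Rhag at 17.6 ± 1.09 TPM. Alas2, the erythroid enzyme that starts haem synthesis, had 0 counts in both libraries, and Slc4a1 stayed below 1 TPM. In the megakaryocyte list 7 of 12 genes were detected in both, with a median of 5.23 ± 2.99 TPM, led by the integrin Itga2b at 74.9 ± 35.5, Pf4, a platelet chemokine, at 73.5 ± 30.4, Vwf at 14.3 ± 1.63 and Gp9 at 7.85 ± 6.54 TPM. Gp6 and Ppbp had 0 counts. In the mature neutrophil list 3 of 12 genes were detected in both, at a median of 0.108 ± 0.0177 TPM. The antimicrobial S100a8 stood at 3.33 ± 1.13 TPM, S100a9 at 2.05 ± 0.460 and the chemokine receptor Cxcr2 at 1.27 ± 0.0424, while Ltf, Camp, Ngp and Lcn2 were below 1 TPM. In the list of eosinophils, basophils and mast cells 4 of 14 genes were detected in both, namely Cpa3 at 26.2 ± 6.82 TPM, Hdc at 10.2 ± 8.36, Mcpt8 at 8.92 ± 5.34 and Ms4a2 at 2.21 ± 0.856, and the list median was 0.0150 ± 0.0212 TPM. Haemoglobin genes are near-identical copies, so the division of their reads is an estimate, and 3 of the 15 erythroid genes had no matching symbol.

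Markers of other blood and tissue cells were mostly missing. In the list of monocytes, macrophages and dendritic cells 2 of 15 genes were detected in both libraries, the list median was 0 TPM in each, and the antigen presentation gene H2-Ab1 stood at 7.30 ± 0.919 TPM and the chemokine receptor Ccr2 at 5.04 ± 4.18. H2-Aa had 1 count in replicate 1 and 297 in replicate 2, and Cd74 had 1 and 161, and without replicate 1 the list had 4 detected members. The B cell list had 1 of 12 genes detected in both, Cd79b at 9.89 ± 3.24 TPM, with a median of 0.0050 ± 0.00707 TPM, and Vpreb1 had 66 counts in replicate 1 and 1 in replicate 2. With either library left out, the B cell list had 2 detected members. None of the 14 T and NK cell genes was detected in both libraries (0 of 14), the highest being Lck at 1.73 ± 2.30 TPM, and the list had 1 detected member without replicate 2 and 2 without replicate 1. The stroma and endothelium list had 1 of 12, Pdgfrb at 6.64 ± 0.247 TPM, and 2 without replicate 1. The list of other tissues had 0 of 12, with 11 genes at 0 counts in both libraries and Pou5f1 at 0 counts in replicate 1 and 54 in replicate 2, so that 1 was detected without replicate 1. The medians of the T and NK cell, stroma and other tissue lists were 0 TPM in each library.

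**Figure D1:**
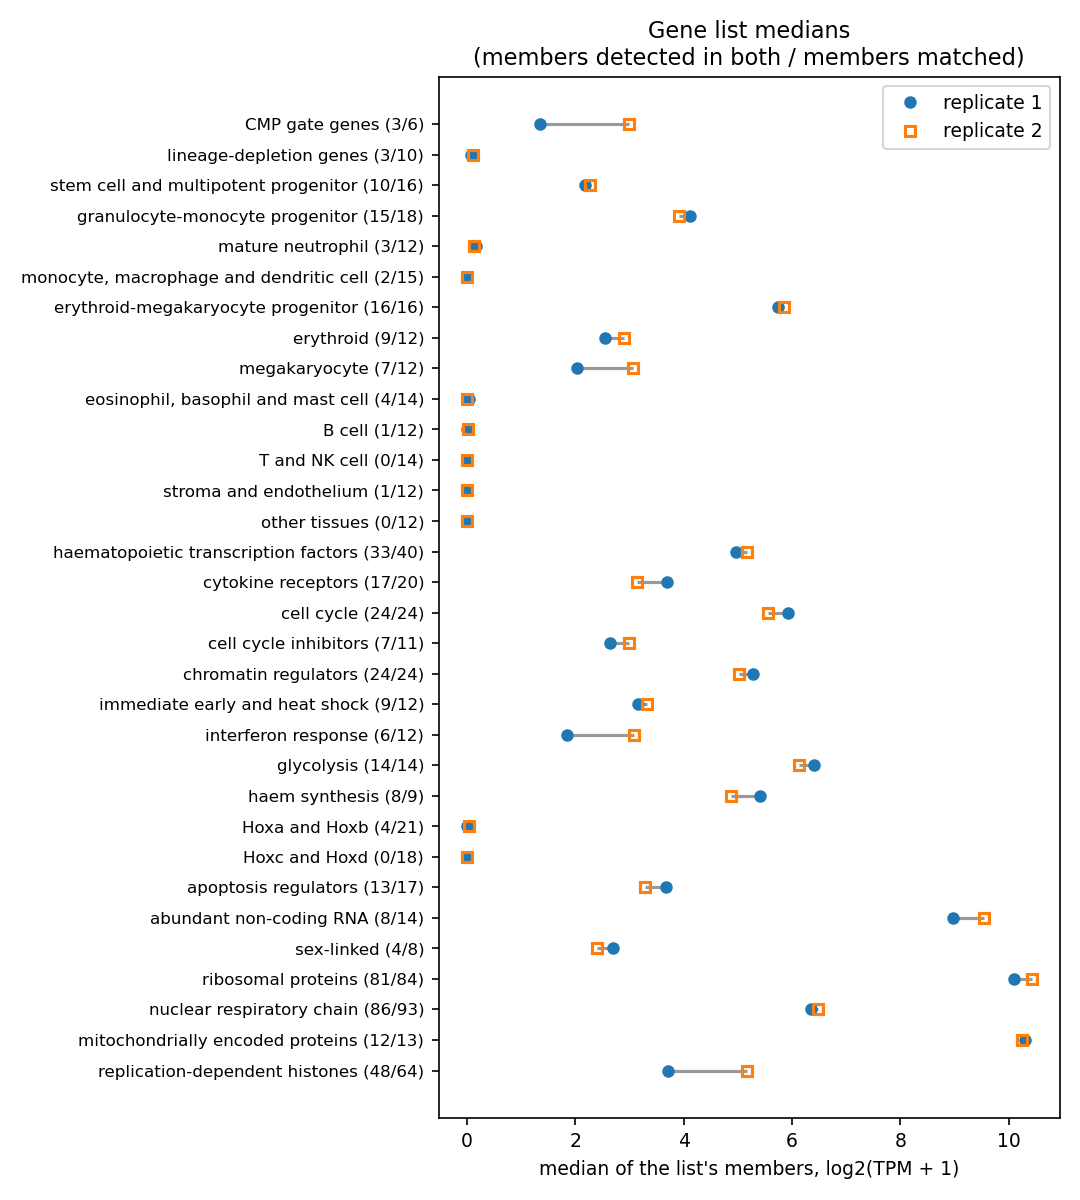
Median of each fixed gene list on the log2 scale of TPM + 1 (horizontal axis) in replicate 1 (filled circles) and replicate 2 (open squares), with the members detected at 1 TPM or more in both libraries over the members matched. The erythroid-megakaryocyte progenitor list stood at 52.2 and 57.2 TPM, and the T and NK cell list at 0 TPM in both libraries.

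Of the 40 haematopoietic transcription factors 33 were detected in both libraries, with a median of 32.7 ± 3.21 TPM. Lmo2 was followed by Myb, a factor of immature blood cells (chromosome 10, 21124935 to 21160984), at 213.7 ± 7.34 TPM, Myc, a driver of growth, at 193.7 ± 52.2 and the Lmo2 partner Ldb1 at 161.4 ± 8.61. Cebpb, Cebpe, Irf4 and Klf4 were below 1 TPM in both libraries. Of the 20 cytokine receptor genes 17 were detected in both, with a median of 9.88 ± 2.85 TPM, led by Kit, Ifngr1 at 71.4 ± 2.84, the erythropoietin receptor Epor at 23.6 ± 5.24 and Cxcr4 at 22.0 ± 0.658 TPM. Il5ra and Il7r had 0 counts in both libraries.

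Erythroid and megakaryocytic regulators stood above the myeloid regulators set beside them. Gata1 (X chromosome, 7959260 to 7978071) was at 53.2 ± 0.926 TPM and Gata2 (chromosome 6, 88193891 to 88207032) at 71.6 ± 23.8, whereas Spi1, which encodes the myeloid factor PU.1 (chromosome 2, 91082390 to 91115756), was at 10.99 ± 3.11 and Cebpa (chromosome 7, 35119293 to 35121928) at 7.69 ± 2.83. The log2 ratio of TPM + 1 was -2.20 ± 0.37 (SE, n = 2) for Spi1 over Gata1 (adjusted p = 0.00131), -2.68 ± 0.41 for Cebpa over Gata1 (adjusted p = 0.000797) and -2.58 ± 0.35 for Spi1 over Gata2 (adjusted p = 0.000525). Gfi1b, a repressor of the erythroid and megakaryocytic lineages, was at 75.3 ± 5.71 TPM and its granulocytic relative Gfi1 at 1.93 ± 2.57, a log2 ratio of -5.05 ± 0.52 (adjusted p = 0.000130). Irf8, a monocyte and dendritic cell regulator, exceeded Gfi1 by a log2 ratio of 3.70, and Cebpa exceeded Cebpb by 2.75. Gfi1 had 5 counts in replicate 1 and 97 in replicate 2, and Cebpb had 1 and 14. The sizes of the ratios with Gfi1 or Cebpb therefore depend on the pseudocount. Cebpa over Cebpe also passed, and as Cebpe had 3 counts in replicate 1 and 0 in replicate 2, its log2 ratio of 2.99 depends on the pseudocount and is no bound. Gata2 over Gata1 (0.38, adjusted p = 0.256) and Fli1 over Klf1, a megakaryocytic over an erythroid factor (-0.52, adjusted p = 0.187), did not pass the test.

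Among the other pairs, receptors, proteases and enzyme isoforms differed widely. Kit exceeded Flt3 by a log2 ratio of 2.68 ± 0.33 (SE), Mpo exceeded Elane, the neutrophil elastase gene, by 4.70 ± 0.39 and Prtn3 by 2.60 ± 0.38, and Csf2rb exceeded Csf2rb2 by 1.92 ± 0.36. Csf1r stood below Csf3r (-1.26 ± 0.45) and Fcgr3 below Fcgr2b (-1.05 ± 0.38). Ldha, the lactate dehydrogenase gene of glycolytic cells, exceeded Ldhb by 6.76 ± 0.54. Ldhb had 77 counts in replicate 1 and 5 in replicate 2, so the size of that ratio depends on the pseudocount. Myc exceeded Mycn by 4.07 ± 0.36, Ezh2 exceeded Ezh1 by 2.92 ± 0.36, and Runx1 exceeded Runx2 by 1.78 ± 0.41 and Runx3 by 1.10 ± 0.29. Ikzf1 over Ikzf2 (1.58 ± 0.41), Dnmt1 over Dnmt3a (1.40 ± 0.32), Hoxa9 over Hoxb4 (1.32 ± 0.40), Tet3 over Tet2 (1.13 ± 0.39) and Cdk4 over Cdk6 also passed. For pairs whose second gene had 0 counts in both libraries, lower bounds came from the floor of 3 counts per library. By that floor Cd34 was at least 344.5-fold above Procr, Ddx3y at least 458.9-fold above Xist and Alas1 at least 73.0-fold above Alas2 in the library with the lower bound. These bounds cover counting error alone. Of 11716 genes with 50 or more counts in a library, 369 had 0 in the other, so 0 counts need not mean so low a level.

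Of the 32 fixed pairs 26 passed at an adjusted p of 0.05 in the limma moderated test against the spread between the libraries, 19 with the first gene higher and 7 with the second, and 16 of them differed by 4-fold or more. All 32 ratios had the same sign in both libraries, including Dnmt3a over Dnmt3b (0.24, adjusted p = 0.491), Tet2 over Tet1 (-0.46, adjusted p = 0.269) and Mcl1 over Bcl2 (0.72, adjusted p = 0.0666), which did not pass. Without correction for transcript length 28 pairs passed, 25 of them shared with the 26, and Cdk6 over Cdk4 turned from -1.13 (adjusted p = 0.00461) to 0.61 (adjusted p = 0.00432). Csf1r over Csf3r then no longer passed, while Gata2 over Gata1, Fli1 over Klf1 and Dnmt3a over Dnmt3b did. Fli1 over Klf1 passed with the opposite sign, and Tet2 over Tet1 and Mcl1 over Bcl2 turned sign without passing.

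**Figure D2:**
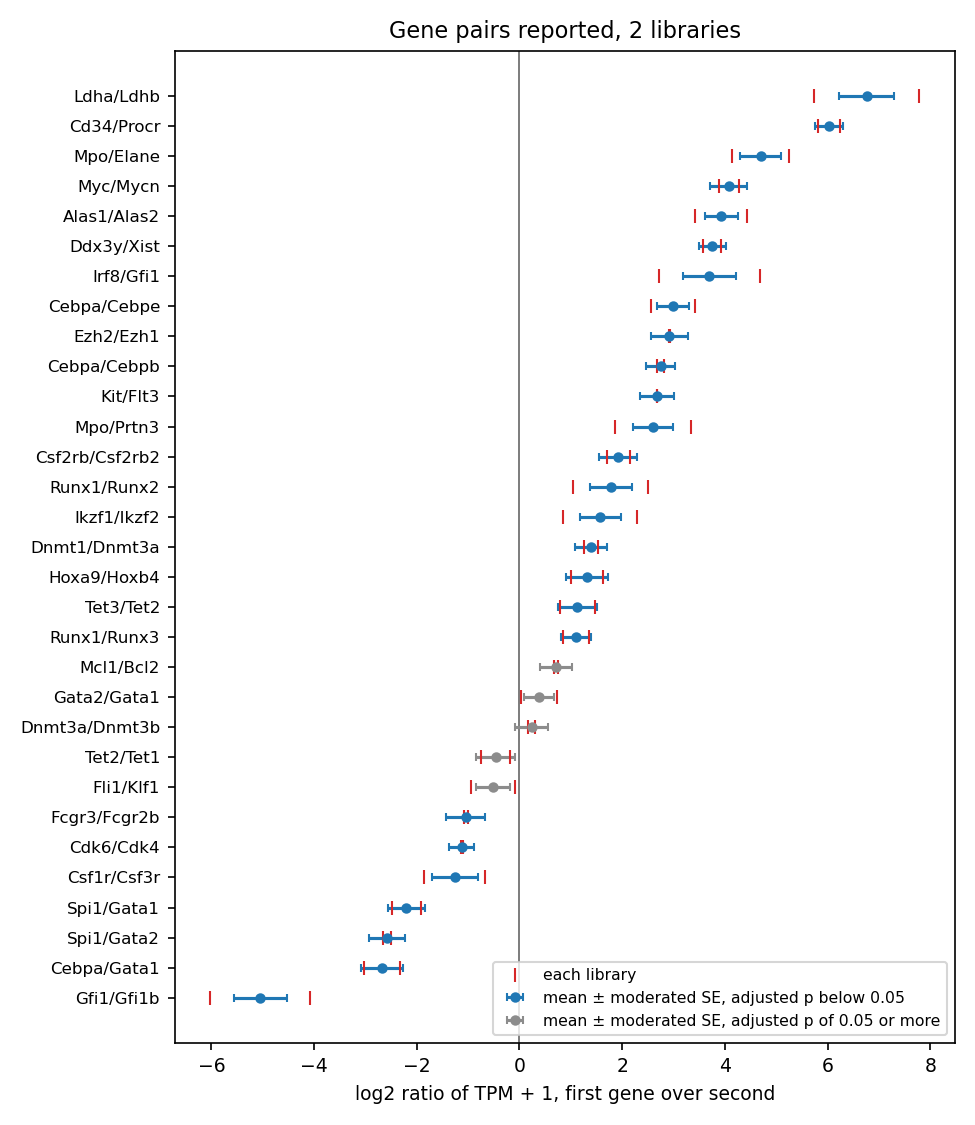
Log2 ratio of TPM + 1 (horizontal axis) of the first over the second gene of each pair reported in each library (ticks), with the mean of both and its moderated SE (circles and bars, grey where the adjusted p was 0.05 or more). Ldha over Ldhb reached 6.76 and Gfi1 over Gfi1b -5.05, and every pair drawn had 1 sign in both libraries.

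Genes of proliferation and core metabolism were abundant. All 24 cell cycle genes were detected in both libraries, with a median of 53.0 ± 9.63 TPM, led by the tubulin regulator Stmn1 at 352.3 ± 3.01, Tubb5 at 294.4 ± 40.6, the replication clamp Pcna at 205.9 ± 6.96 and the helicase gene Mcm3 at 191.4 ± 21.8 TPM. Of the 11 cell cycle inhibitors 7 were detected in both, with a median of 6.10 ± 1.25 TPM and with Trp53 at 113.9 ± 13.1, Rb1 at 22.8 ± 4.69, Cdkn1b at 9.25 ± 2.81 and Cdkn2d at 8.71 ± 2.05, whereas Cdkn1c, Cdkn2a and Cdkn2b were below 1 TPM. All 24 chromatin regulators (median 34.7 ± 4.36 TPM) and all 14 glycolysis genes (median 76.2 ± 10.4 TPM) were detected in both libraries. Among them the remodeller Chd4 stood at 87.2 ± 19.6, Ezh2 at 78.7 ± 11.5, Gapdh at 574.3 ± 12.4 and Ldha at 267.9 ± 2.31 TPM. Of the haem synthesis genes 8 of 9 were detected in both (median 34.9 ± 9.33 TPM), with Urod at 61.5 ± 28.3. The apoptosis list had 13 of 17 (median 10.3 ± 2.18 TPM), with Bak1 at 39.7 ± 11.7, and Bcl2a1a, Bcl2a1b and Bcl2a1d had 0 counts. Immediate early and heat shock genes (9 of 12, median 8.48 ± 0.721 TPM) and interferon response genes (6 of 12, median 5.02 ± 3.43 TPM) were led by Dusp1 at 25.3 ± 20.1 and Ifitm3 at 74.8 ± 12.9 TPM. Among all 32 lists, 12 had medians within the top 2.5% of random lists in both libraries, and 9 against random lists of detected genes alone.

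Genes of translation made up most of the 20 highest nuclear protein-coding genes. The ribosomal protein list had 81 of 84 genes detected in both libraries and a median of 1232 ± 199.2 TPM, with Rps12 at 3782 ± 467.0, Rpl41 at 2684 ± 169.2, Rps24 at 2632 ± 168.2 and Rpl23a at 2426 ± 266.7. Rps27, Rpl26, Rps18, Rpl32, Rps19, Rps15, Rps27a, Rpl13a, Rplp1, Rps2 and Rpl10 were also among the 20 highest, between 2304 and 1852 TPM, together with Eef1a1, the elongation factor that brings tRNA to the ribosome, at 4799 ± 133.1 TPM. Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366927 to 123462666), headed that group at 10953 ± 8162 TPM, which was 1060 times the median of 16 other genes of its kind. The nuclear respiratory chain list had 86 of 93 genes detected in both (median 84.3 ± 5.43 TPM), with Atp5b at 700.7 ± 79.2 and Uqcrh at 377.0 ± 114.7. The mitochondrially encoded protein genes had 12 of 13 (median 1239 ± 31.3 TPM), with mt-Co1 at 3612 ± 717.0 TPM.

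Ribosomal RNA took a large part of the counts. Gm42418, a locus annotated as a long non-coding RNA over an 18S ribosomal repeat (chromosome 17, 39846958 to 39848788), took 35.5 ± 3.67% (SD, n = 2) of the counts, and the mitochondrial ribosomal RNA genes 15.3 ± 1.85%. Nuclear protein-coding genes took 44.6 ± 0.983% of the counts and 38.5 ± 1.06% of TPM. Without Lars2 they took 39.4% of the counts in replicate 1 and 43.8% in replicate 2 (41.6 ± 3.06%). Ribosomal protein genes took 4.22 ± 0.747% of the counts, mitochondrially encoded protein genes 1.20 ± 0.170%, Lars2 2.97 ± 2.08% and histone genes 0.0981 ± 0.0457%. Among abundant non-coding RNAs, 8 of 14 matched genes were detected in both (median 622.2 ± 171.1 TPM). Rn7sk, which holds back transcription elongation, stood at 39185 ± 11119 TPM, Rpph1, the RNA of ribonuclease P, at 5228 ± 4041, and Rn7s1 and Rn7s2, copies of the signal recognition particle RNA with equal values in the tables, at 2508 ± 7.79 each. Rny1, Rny3, Meg3 and H19 stayed below 1 TPM. Only RNA over 200 nucleotides was kept, so low values of shorter RNAs cannot be read as low expression. Spike-ins took 0.0220 ± 0.00499% of the counts, and 15 of the 96 spike-ins had counts in both libraries. In replicate 1 21 spike-ins had counts and in replicate 2 17. Spearman's rho was 0.805 across all 96, most of them at 0 counts in both libraries, so it partly reflects shared values of 0. The median absolute log2 ratio was 0.33 across the 15 but 1.25 across the 20 at mean counts of 10 to 1000, of which 7 had 0 counts in a library.

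Most detected protein-coding genes were shared by the libraries. At 1 TPM or more, 10095 protein-coding genes were detected in replicate 1, 10314 in replicate 2 and 9639 in both, and 171 long intergenic and antisense RNAs were detected in both. Across the 21474 protein-coding genes Pearson's r of log2(TPM + 1) was 0.964 and Spearman's rho 0.954, and r was 0.893 across the 10770 detected in either library; genes are not independent replicates. The spread was wider at low levels, where 58.6% of 744 genes at a mean of 1 to 2 TPM lay within 2-fold against 95.5% of 1190 genes at 50 TPM or more. The biological coefficient of variation was 0.759 over all genes used, 1.17 at mean counts of 30 to 100, and 0.138 at 3000 to 10000.

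**Figure D3:**
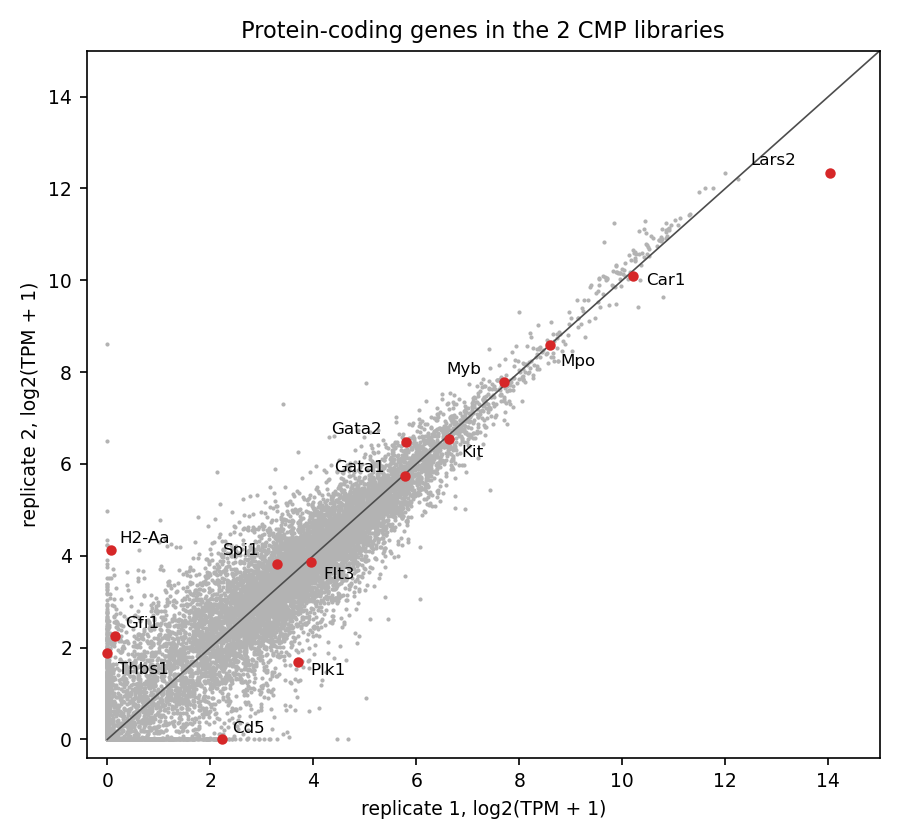
Protein-coding genes on log2 scales of TPM + 1 in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with the line of equal values and some genes labelled. Mpo and Kit lie near the line, while Thbs1 (0 and 312 counts) lies on the vertical axis.

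Between the libraries, genes of several lists leaned one way, by an exact binomial test that measures counting noise alone and called 10617 of 13616 genes. Against the spread between the libraries, with the edgeR exact test, 0 genes differed. That spread was estimated from these same 2 libraries and contains the difference tested, so the 0 cannot show that the libraries agree. Replication-dependent histone genes, which package newly made DNA, stood higher in replicate 2 for 45 of 58 tested genes and higher in replicate 1 for 6, with a median log2 ratio of 1.02. Hist1h4c was 6.35-fold, Hist1h4d 2.27-fold and Hist1h1e 2.02-fold higher in replicate 2. Cell cycle genes leaned the other way, with 21 of 24 higher in replicate 1 and 1 in replicate 2 (median -0.42), including Mcm3 at 1.39-fold and Pcna at 1.13-fold, and Plk1, chosen after its values were seen, at 5.57-fold. Of the 11 tested genes of the immediate early and heat shock list, 8 of the 9 immediate early genes were higher in replicate 2, among them Zfp36 at 3.15-fold, Dusp1 at 2.39-fold and Jun at 2.10-fold, while both heat shock genes were higher in replicate 1, Hspa1a, also chosen after its values were seen, by 6.89-fold. Megakaryocyte genes were higher in replicate 2 for 8 of 10 tested and in replicate 1 for 1, with Gp9 at 3.67-fold, Itga2b at 2.05-fold, Pf4 at 1.72-fold and Vwf at 1.58-fold.

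Of 39 tested transcription factors 23 were higher in replicate 2 and 9 in replicate 1, and of 81 ribosomal protein genes 65 and 10. Among the gate genes Cd34 was 1.40-fold higher in replicate 1, Fcgr3 6.30-fold and Fcgr2b 2.40-fold higher in replicate 2, and Kit did not pass the test (adjusted p = 0.117, exact binomial test). Adjusted over the list alone, 52 histone, 22 cell cycle, 10 immediate early and heat shock, 9 megakaryocyte, 32 transcription factor, 76 ribosomal protein and 3 gate genes differed, against 51, 22, 10, 9, 32, 75 and 3 over all genes tested. Total counts include Gm42418, which took 38.1% of all counts in replicate 1 and 33.0% in replicate 2. Lars2, also included, took 4.44% and 1.49%. Scaling by total counts shifted all log2 ratios by 0.20 towards replicate 2. It left the direction of those lists in place, with 48 and 4 for histones, 5 and 14 for cell cycle genes, 9 and 2 for immediate early and heat shock genes, 8 and 1 for megakaryocyte genes, 29 and 6 for transcription factors and 75 and 3 for ribosomal protein genes. It turned the balance of cytokine receptors from 4 and 10 to 7 and 6, of chromatin regulators from 7 and 13 to 12 and 5, of stem cell genes from 3 and 7 to 6 and 4, of apoptosis regulators from 3 and 9 to 5 and 4 and of erythroid genes from 4 and 5 to 5 and 4. Glycolysis genes went from 5 and 5 to 10 and 2 and stroma genes from 1 and 2 to 2 and 2.

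Single genes with the largest differences had counts in 1 library alone. In replicate 2 mt-Nd4l, a mitochondrial complex I gene, was at least 367.5-fold higher, Gm10163 177.5-fold, Hist1h4m 144.5-fold, Gm28438 141.2-fold, the nucleoside diphosphate kinase gene Nme3 113.5-fold, Thbs1, which encodes a thrombospondin of platelets, 102.0-fold, Rpl7a-ps11 81.4-fold, Hist1h2br and Gm2260 79.1-fold and Adamtsl5 72.3-fold, each computed against the floor of 3 counts. In replicate 1 the glycosyltransferase gene B3gnt2 was at least 291.9-fold higher, the unnamed gene ENSMUSG00000103235.1 168.2-fold, Gm2274 141.4-fold, Gm10240 and Gm13370 138.7-fold, Gm9797 127.8-fold, the zinc finger gene Zfp960 87.3-fold, Gm28551 74.4-fold, Acad12 64.2-fold and Pcdhga1 61.2-fold. Of these 20 genes 18 had a near-identical stretch in another gene, all but Adamtsl5 and ENSMUSG00000103235.1, and whether the division of shared reads gave their 0 counts was not tested, so their folds are bounds for the deposited counts alone. In all, 369 of 11716 genes with 50 or more counts in a library had 0 in the other, 165 of them present in replicate 1 and 204 in replicate 2. Of the 362 such genes with a transcript sequence in the reference, 44.5% had a near-identical stretch in another gene.

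By the exact binomial test of counting noise 10617 of 13616 genes differed between the libraries at an adjusted p of 0.05, 5516 higher in replicate 2 and 5101 in replicate 1, and 4078 of them differed by 2-fold or more. With total-count scaling 10744 differed, 7134 higher in replicate 2 and 3610 in replicate 1. Measured against the spread between the libraries with the edgeR exact test at the common dispersion, 0 genes differed, and 1541 had an unadjusted p below 0.05. The common dispersion was itself estimated from the difference between these 2 libraries, so this test cannot decide which genes differ. The labels give the libraries no difference other than the replicate number and sample identifiers, so these counts compare 2 libraries and no conditions.

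**Figure D4:**
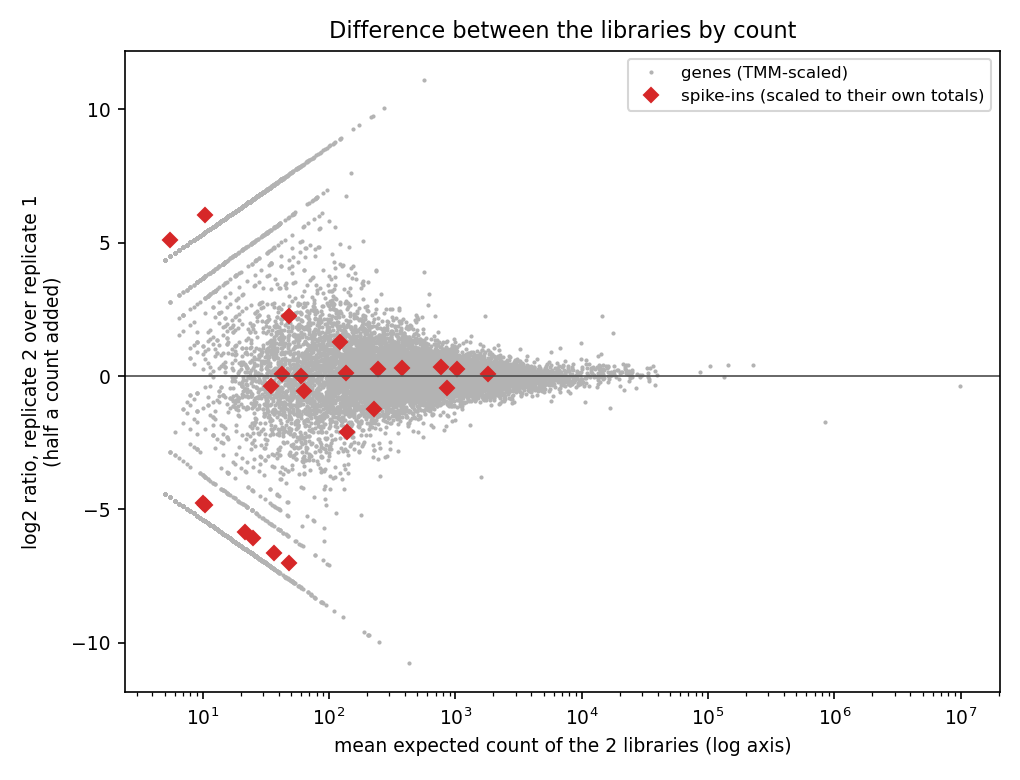
Log2 ratio of replicate 2 over replicate 1 (vertical axis) against mean count (horizontal axis, log scale) for the genes tested between the libraries (grey points, TMM-scaled) and the spike-ins (diamonds, scaled to their own totals). Genes with 0 counts in 1 library form the outer edges, with B3gnt2 at -10.78 and mt-Nd4l at 11.11 with 0.5 counts added.

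Leading transcripts of several regulators were the same in both libraries. Gata1-201 took 100% of the Gata1 TPM in each library, as did Mcl1-201 for Mcl1, and ENSMUST00000170089.3 took 88.9 ± 0.559% (SD, n = 2) of Gata2, Tal1-201 99.0 ± 1.37%, Fli1-201 94.2 ± 8.18%, ENSMUST00000051477.8 90.5 ± 10.2% of Cdc42, Spi1-201 87.8 ± 14.04% and Lmo2-208 87.5 ± 8.60%. Weaker leads were shared for Csf1r-201 (79.3%), Pkm-201, the transcript of a pyruvate kinase (75.2%), Cd34-201 (72.9%), ENSMUST00000113846.5 of Erg (64.9%), Flt3-201 (64.4%), Cd44-207 (54.9%), Ikzf1-204 (54.7%), Myb-203 (54.3%), Hoxa9-201 (53.4%), Mpo-203 (51.3%), Ezh2-201 (39.0%) and Runx1-207 (37.4%). Runx1-207 is annotated as a processed transcript and not as protein-coding. In 8 of the 28 fixed genes with enough counts the leading transcript differed, namely Kit, Ptprc, Meis1, Dnmt3a, Dnmt3b, Bcl2l1, Csf3r and Etv6. The replicate 1 leaders of Ptprc, Meis1 and Dnmt3b are annotated as retained introns, and that of Bcl2l1 as a processed transcript. Kit-201 took 66.0% of Kit in replicate 1 and 0% in replicate 2, where Kit-204 led. Cebpa, Csf2ra and Sox4 passed 50 counts in both libraries but had 1 annotated transcript, and Fcgr3 had 15 counts in replicate 1.

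Across all 7354 genes with at least 2 transcripts and 50 counts in each library, 4390 (59.7%) had the same leading transcript, against 23.2% if each transcript were equally probable. The share rose with depth, from 49.1% at a lower count of 50 to 200 to 81.1% at 5000 or more. By Fisher's exact test the share of the leading transcript differed between the libraries in 5815 genes (79.1%) and in 24 of the 28 fixed genes. Transcript values divide reads among overlapping isoforms by estimate, and the test measures counting noise alone.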

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

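The searches of Lars2 for ribosomal RNA, the comparison of histones with random lists and the S-phase test were chosen only after the result was seen, and the other tests were set before. The labels name no biological contrast between the libraries, so no biological explanation given by the design was tested. The rule by which the spike-in ratio was read was also rewritten after its value was seen, and the stricter reading is given. The tRNA entries of the gene tables, used in no comparison, held 21 counts in replicate 2, all on 1 of 26248 entries, against 0 in replicate 1, above the 3 counts that a count of 0 allows.

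Lars2 stood 1060 times above the median of 16 other genes whose symbols end in ars2 (2252 in replicate 1, 506.2 in replicate 2), the highest of those being Iars2 at 21.6 TPM. With the others at 21.6 TPM or less, high output was not general to genes of this kind. That ratio restates the pattern, so it is no separate test of its cause. The longest alignment at 90% identity or more between Lars2 transcripts and 18S or mitochondrial ribosomal RNA was 20 bases. Shared sequence with those RNAs is thereby argued against. Shared 28S sequence stays open, because 0 transcripts named for 28S or 45S ribosomal RNA were in the reference to search.

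Among genes with 50 or more counts in a library, 369 had 0 in the other, such as B3gnt2 and Adamtsl5. The highest of 100 Poisson simulations gave 0. Counting noise of reads alone does not account for these genes, though cut-offs of 50 and 0 made that outcome near certain beforehand. Capture of few molecules may contribute: the spread of 20 spike-ins was 1.52 times that of genes at matched counts, but its interval of 0.446 to 4.50 leaves this open. Of these spike-ins 35% had 0 counts in a library against 14.2% of matched genes. Reads shared between near-identical genes stay open too, since 44.5% of the genes (95% Wilson interval 39.4 to 49.6) had a near-identical stretch elsewhere against 31.2% of count-matched genes, and the rest had none.

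Replication-dependent histone genes stood higher in replicate 2, with a median log2 ratio of TPM of 1.05 over 57 genes. They were chosen after all lists were seen, as the largest shift among the 20 lists compared on the TPM scale. Lists with few members at a mean of 1 TPM or more were not compared on that scale. Allowing for that choice, a median as large in either direction arose in any of the 20 lists compared in 2.44% of 10000 rounds of random lists matched on level. Those rounds drew genes singly. Histone genes such as Hist1h4m and Hist1h2br have a near-identical stretch in another gene, and reads shared between genes are divided by estimate. The members are thus not separate measures, and the rounds cannot decide whether noise accounts for the shift. Length and GC content do not account for its size. Lists matched on these and on level had a median of 0.07, against 0.97 for the 45 matched members. Of 10000 such lists 0% reached 0.97, though these lists too drew genes singly. Of 11 S-phase genes such as Pcna, Mcm3 and Tk1, 2 were higher in replicate 2 and 9 in replicate 1. Their median on the TPM scale was -0.26, with a bootstrap 95% interval over genes, not libraries, of -0.52 to -0.09. That direction is opposite to the one predicted from more cells in S phase in replicate 2. These genes belong to the cell cycle list already seen to lean to replicate 1, so the test adds no independent evidence. What raised the histone genes stays open, and non-polyadenylated RNA capture was not tested.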

How the results depend on the processing

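Pair calls at other pseudocounts, posterior means or without trend kept their direction and their side of the threshold. The 15 spike-ins with counts in both libraries stayed 15 at 5 or more counts. Numbers of detected genes fall by construction at higher TPM thresholds and were held to a loose fold limit alone. Agreement across genes moved to 0.959 with a pseudocount of 0.1 and to 0.893 over genes at 1 TPM or more in a library. The 10617 genes differing fell to 0 in the edgeR exact test at the common dispersion, which sets the difference against the spread it is part of. Nuclear protein-coding genes took 38.5% as a share of TPM, where long transcripts weigh less. Genes with the same leading transcript came to 62.5% at 200 or more counts and 65.8% over protein-coding transcripts. At a TPM threshold of 5, by construction stricter, the lists held 6 detected members for stem cells, 0 for mature neutrophils, 1 for monocytes, macrophages and dendritic cells, 5 for erythroid cells, 4 for megakaryocytes, 2 for eosinophils, basophils and mast cells, 11 for cytokine receptors and 1 for Hoxa and Hoxb. Posterior mean TPM gave 3 for B cells, 1 for T and NK cells and 1 for other tissues. The TPM threshold of 0.5 gave 2 for stroma, and TPM rescaled over nuclear protein-coding genes gave 3 for stroma and 7 for Hoxa and Hoxb. Leaving out each library gave 2 to 4 for monocytes, 2 to 2 for B cells, 1 to 2 for T and NK cells, 1 to 2 for stroma and 0 to 1 for other tissues. Without length correction the log2 ratios of 4 reported pairs reversed, to 0.59 for Fli1 over Klf1, 0.41 for Tet2 over Tet1, 0.61 for Cdk6 over Cdk4 and -0.053 for Mcl1 over Bcl2. A further 87 values moved, mainly list medians and single genes under rescaled TPM, 3 pairs newly passed (Gata2 over Gata1, Fli1 over Klf1 and Dnmt3a over Dnmt3b) and Csf1r over Csf3r no longer did, all without length correction. Where no cause is stated, the cause was not tested. With 1 library left, agreement, differing genes, the number of pairs passing and leading transcripts have no value. Against random lists of detected genes, 9 lists in place of 12 lay within the top 2.5% in both libraries, the genes drawn being higher by construction. Depth limits a gene with 0 counts to 0.104 CPM in replicate 1 and 0.114 in replicate 2. At 1 to 2 TPM 16.4% of genes had 0 counts in a library, and the cause was not tested.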

Other observations

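The comparison of list shifts with lists matched on level was chosen after the values were seen, and the values here carry no explanation. Immediate early and heat shock genes had a median log2 ratio of TPM, replicate 2 over replicate 1, of 0.87, at percentile 99.86 of 10000 lists matched on level, with 8 of 10 genes higher in replicate 2. Megakaryocyte genes stood at 0.71 and percentile 99.4, with 9 of 10 higher in replicate 2, ribosomal protein genes at 0.22 and percentile 99.5, and cell cycle genes at -0.28 and percentile 0.67. The median over all 10394 genes at a mean of 1 TPM or more was 0.02. The percentiles were not adjusted for the number of lists, and list members are not independent replicates.

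Of the short non-coding RNAs whose shares were read, Rpph1 took 3.40 times the share of counts in replicate 2 that it took in replicate 1, Rn7sk 1.504 times and Rmrp 1.32 times, whereas Rn7s1 and Rn7s2 together took 0.984 times. Histone genes took 1.98 times the share, ribosomal protein genes 1.29 times and Lars2 0.337 times. By length, the median log2 ratio was 0.25 over 131 protein-coding genes shorter than 500 bases and -0.07 over 3052 genes of 4000 bases or more.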
